A study of Homo sapiens with 12 samples.

How the data were processed

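Total RNA from the human bladder cancer cell lines RT112 and 5637 was measured on Affymetrix whole-transcript arrays, with 3 arrays for each line treated with CM272 and 3 for each line left untreated, 12 arrays in 4 groups. The dose was the inhibitory concentration IC50 of CM272 per the labels' protocols. The duration of treatment was not given in the sources used here. The labels number the replicates but do not say whether they came from separate cultures, so p-values measure the spread between these arrays only.

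The authors deposited 1 table of log2 values with 70523 rows and 12 columns. The values were made with RMA in Affymetrix Expression Console, per the submitters' processing notes. The highest value of an array lay between 19.56 and 19.93. Whether a transformation beyond RMA set this scale is not known here. All log2 changes and folds are therefore those of the deposited scale. Versions, the annotation release and a genome build were not given in the sources used here, so no coordinates are printed. Array precision is limited by the number of arrays, 3 per group. Transcript clusters filled 67528 rows, and 2995 rows held control, spike-in, exon and other probe sets. GEO's platform annotation paired 23781 probe sets with 1 gene symbol and 1543 with several. No gene was given for 45199. No gene was named from a probe set with several symbols. Of 22465 genes tested, 22167 had their symbol in the RefSeq gene table of assembly GRCh38.p14, which was used for names, gene types and the order of neighbouring genes, and 17085 were protein coding. For the 479 genes with more than 1 probe set, the brightest over the arrays in the fit was taken.

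Beyond the first rows of the table, the transcript-cluster values of the untreated 5637 arrays did not match those of the other arrays in the same rows. Over the 67528 transcript clusters, the mean of the untreated 5637 arrays correlated with the mean of the treated 5637 arrays at r = 0.0274, while over the 2995 other rows r was 0.966. The columns were compared in 1125 windows of 60 consecutive rows, each set against the treated 5637 mean at every offset up to 300 rows. In 683 windows (60.7%) r exceeded 0.8, with a median offset of -152 rows. Of these, 3 matched in the same rows and 680 at another offset, against 0 windows when the row order was reversed. Because a row of these columns cannot be given a gene without guessing from its values, the untreated 5637 arrays entered no comparison of genes. The comparisons of treated with untreated 5637, of the response between lines, of the untreated lines, of calls in both lines and of fold changes between lines had been planned and were not made. Treated 5637 was compared with treated RT112 in their place, a comparison chosen after seeing the data.

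Exact ties set the treated arrays apart from the untreated ones. Treated arrays of different lines shared exactly equal values in a median of 7330 rows per pair of arrays, and treated and untreated RT112 arrays in a median of 0. Untreated arrays hardly tied with each other, in a median of 12 rows within RT112 and 5 within 5637. In treated RT112, 2726 genes (12.1%) had the same value in all 3 replicates, and in untreated RT112 0 genes did. Such genes have a replicate SD of 0 in that group. Leaving out the genes with equal replicates is among the alternatives. Any difference in processing between treated and untreated arrays coincides with the treatment in these values. Each RT112 result was therefore computed in 3 scalings: the deposited values, arrays centred on their medians, and quantile normalization over the 12 arrays. Each scaling acts on whole arrays, so none removes a shift that depends on the probes of a probe set. A gene is called held where all 3 called it in the same direction.

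Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on group means, Benjamini-Hochberg adjustment, adjusted p threshold 0.05). The fit held the 9 arrays of 3 groups, with 6 residual degrees of freedom. The design fixed before the data were examined had all 12 arrays in the fit and chose the brightest probe set over 12 arrays. Both departures followed from the displaced rows, and the fit of 12 arrays is given among the alternatives. The 27 gene lists, with 666 measured memberships, were tested with camera at a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry. Named genes followed a rule fixed before the data were examined: for RT112 the 10 highest and 10 lowest log2 fold changes among protein-coding genes past the threshold whose groups did not overlap, the enzymes EHMT2, EHMT1, DNMT1, DNMT3A and DNMT3B, and up to 4 members per list with the smallest adjusted p. Between treated lines the 5 highest and 5 lowest were named. Not every gene that the rule takes is reported here. Members named beyond the rule are said to be so where they appear.

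The procedure was tested on simulated data for the RT112 comparison with 22465 genes. It recovered 54.5% of 66 genes changed by 0.5 on the log2 scale, 92.5% of 67 changed by 1 and all 67 changed by 2, with 15 unchanged genes called. With no general shift, camera called the shifted list and 0 of the others. With all genes shifted by -0.5 it called 3 other lists, so list results on the deposited values are given beside those after quantile normalization. The simulated genes varied independently of each other, so the simulation does not test list calls where genes correlate. Each simulated gene had the same spread in all groups. Calls of genes with equal replicates, as in the treated arrays, were therefore not tested by it. Row displacement was computed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9. Other alternatives were a filter on dim genes, the mean of a gene's probe sets, all probe sets singly, only the groups compared, trend and robust variance, array weights, the replicate number as a block, a threshold of 0.01, a 2-fold minimum, and leaving out each array of the fit.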

Results

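Transcript levels were measured on whole-transcript arrays in RT112 and 5637, established human bladder cancer cell lines, with and without CM272, a dual inhibitor of the histone methyltransferase G9a (EHMT2) and of DNA methyltransferases. Each of the 4 groups had 3 arrays. The study asked how gene expression in these lines differs after treatment with the compound. The median log2 value of an array averaged 5.07 ± 0.03 (SD, n = 3) in untreated RT112 and 4.43 ± 0.02 in treated RT112, 5.38 ± 0.10 in untreated 5637 and 4.38 ± 0.02 in treated 5637. Over transcript clusters, Pearson's r between replicates lay between 0.991 and 0.992 in treated RT112 and between 0.983 and 0.989 in untreated 5637. Between treated and untreated RT112 arrays the median r was 0.933.

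**Figure D1:**
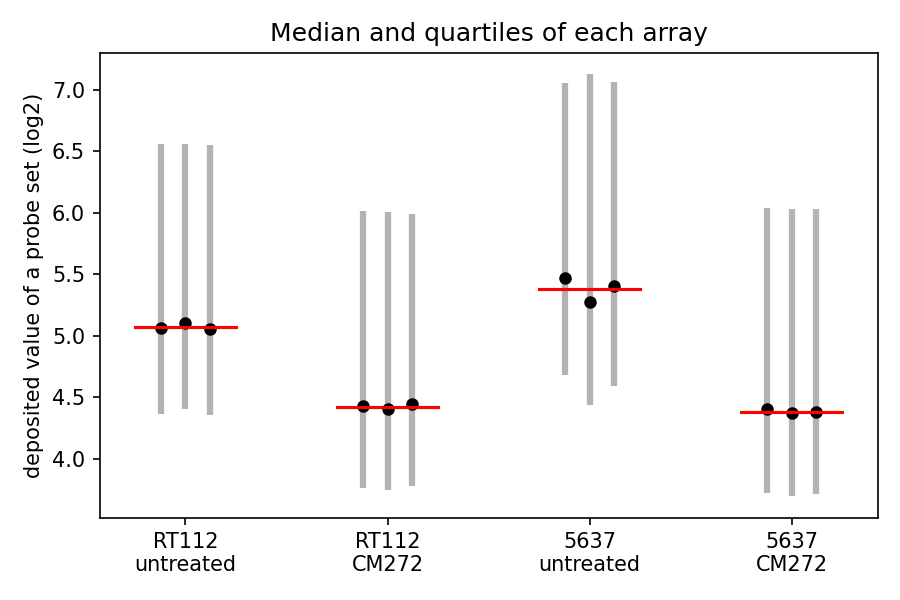
Median (black points) and quartiles (grey bars) of the deposited log2 values of each array, with the mean of the 3 medians of each group as a red line. The treated arrays of both lines lie below the untreated ones, with mean medians of 4.43 and 4.38 against 5.07 and 5.38.

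CM272 against no treatment in RT112 addressed the response of this line to the compound. The immediate-early transcription factor gene FOSB rose from 5.56 ± 0.05 to 12.47 ± 0.44 (SD, n = 3), a log2 change of 6.91 ± 0.18 (SE; adjusted p = 4.31e-08, limma), and of 7.13 after quantile normalization. TEX14, a gene of germ-cell intercellular bridges, rose by 8.23 ± 0.21. SCD, which encodes stearoyl-CoA desaturase, fell from 14.81 ± 0.19 to 8.60 ± 0.27, a log2 change of -6.20 ± 0.14 (adjusted p = 4.17e-08). The basal keratin gene KRT14 fell by 4.56 ± 0.09 and SPP1, which encodes osteopontin, fell by 3.41 ± 0.07. After quantile normalization the changes were 8.48 for TEX14, -5.78 for SCD, -4.17 for KRT14 and -3.28 for SPP1.

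Among the 10 highest changes, 6 belonged to USP17-like deubiquitinase genes, near-identical copies of a repeated unit: USP17L12, USP17L18, USP17L4, USP17L19, USP17L21 and USP17L15, with log2 changes between 6.96 and 8.15. Their untreated levels, at most 4.14, lay below the median of the untreated arrays, so the sizes of these rises are lower bounds where those levels are background. Probe sequences were not used here, so which of these copies rose is uncertain. The olfactory receptor gene OR2B6, also among the 10 highest, rose by 5.95 ± 0.50, and its untreated level and that of TEX14, both 4.56, lay below that median too. Among the 10 lowest were the aldo-keto reductase genes AKR1B10 (-4.25 ± 0.18) and AKR1C3 (-3.49 ± 0.04) and the fatty acid hydroxylase genes CYP4F11 (-4.23 ± 0.07), CYP4F3 (-3.51 ± 0.10) and CYP4F2 (-3.24 ± 0.08). TSPAN7 fell by 3.66 ± 0.12 and SERPINB13 fell by 3.30 ± 0.05 to 4.32, below the median of the treated arrays, so that the size of its fall is a lower bound where that level is background. Each of the genes named here was called in the same direction in all 3 scalings. For the rises this adds little, since every gene called higher on the deposited values was held.

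**Figure D2:**
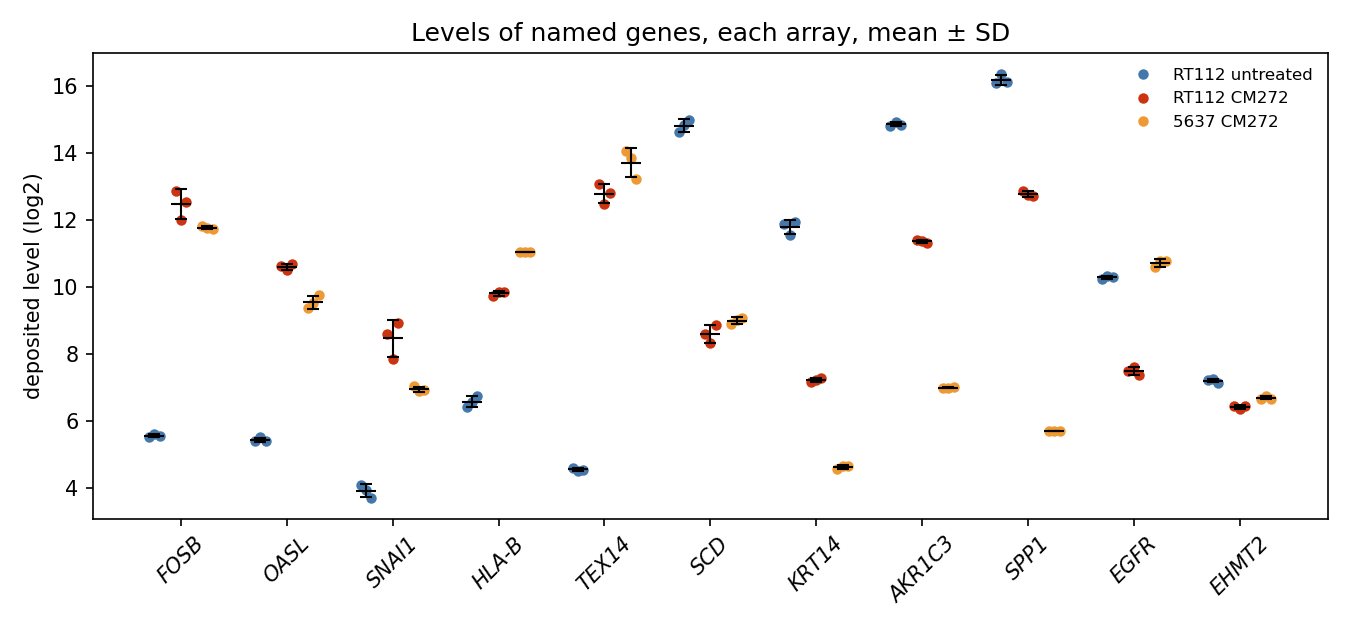
Deposited log2 levels of named genes in untreated RT112 (blue), treated RT112 (red) and treated 5637 (orange), each point an array and each bar the mean ± SD of 3 arrays. FOSB rose from 5.56 to 12.47 in RT112 and SCD fell from 14.81 to 8.60, while EHMT2 moved from 7.21 to 6.42.

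Of 22465 genes, limma called 2433 higher and 16660 lower in treated RT112 on the deposited values, 87.3% of calls being lower. After quantile normalization 7336 were higher and 7984 lower (52.1% lower), and with arrays centred on their medians 8937 and 6285 (41.3% lower). The median log2 change of all genes was -0.57 on the deposited values, 0.08 after centring and -0.02 after quantile normalization, and the deposited changes are read relative to that shift. Centring adds the same amount, the difference between the array medians, to the log2 change of every gene, so it makes falls smaller and rises larger than the deposited values given here. In all 3 scalings 2433 genes were higher and 6285 lower, 642 and 594 of them by at least 2-fold in each scaling and 170 and 48 by at least 4-fold. The held genes were all those called higher on the deposited values and all those called lower after centring. For each direction, the 3 scalings together were therefore no stricter than that 1 scaling. The ERCC control probe sets, whose use as a spike-in was not given in the sources used here, had a median log2 level of 3.71. Tested in the same way, 15 of these 92 probe sets (16.3%) were called in all 3 scalings, 2 of them (2.17%) by at least 2-fold and 1 (1.09%) by at least 4-fold. Of all 22465 genes 38.8% were called, 1236 genes by at least 2-fold and 218 (0.970%) by at least 4-fold. The difference between these shares was not tested, and the median level of the genes, 5.20, was higher than that of the control probe sets. After quantile normalization the log2 changes had an SD of 0.60 over the control probe sets and 0.71 over the genes. By this measure the control probe sets spread nearly as widely as the genes.

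Among the enzymes that the compound targets, EHMT2, which encodes G9a, fell by 0.79 ± 0.05 on the log2 scale and by 0.29 after quantile normalization, with a change of -0.14 after centring (adjusted p = 0.0231, limma), and was called lower in all 3 scalings. The other targets were not called alike. EHMT1 changed by -0.46 ± 0.06 on the deposited values and by 0.06 after quantile normalization, DNMT3A by -0.68 ± 0.05 and -0.08, DNMT1 by 0.03 ± 0.04 and 0.19, and DNMT3B by -0.02 ± 0.08 and 0.59. After centring the changes were 0.19 for EHMT1, -0.03 for DNMT3A, 0.68 for DNMT1 and 0.62 for DNMT3B. Of the 25 measured genes of G9a, DNMT and repressive chromatin machinery, 4 rose and 6 fell in all scalings. EZH2, the Polycomb methyltransferase gene, rose by 1.33 ± 0.06, and CBX3, which encodes a heterochromatin protein, fell by 1.70 ± 0.05. The list as a whole did not pass (camera adjusted p = 0.386 on the deposited values and 0.859 after quantile normalization).

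Antigen presentation by MHC class I was among the lists whose genes stood higher than other genes, with camera adjusted p = 4.36e-07 on the deposited values and 0.00103 after quantile normalization, and adjusted p = 0.136 with an estimated correlation. Of 21 measured members, 9 rose in all scalings and 0 fell. HLA-B rose by 3.23 ± 0.08, HLA-E by 3.22 ± 0.09, HLA-C by 2.57 ± 0.08 and B2M, the light chain of class I molecules, by 1.05 ± 0.03. HLA genes resemble each other in sequence, so their separate values are uncertain. Among 20 checkpoint and NKG2D ligand genes 8 rose and 4 fell (adjusted p = 0.000401, 0.0423 after quantile normalization and 0.0999 with an estimated correlation). Centring left this list at adjusted p = 0.058. The ligand genes MICB and ULBP2, recognised by natural killer cells, rose by 2.56 ± 0.05 and 1.77 ± 0.06, and TNFSF9, which encodes the ligand of 4-1BB, by 3.65 ± 0.15. PVR fell by 0.88 ± 0.05, and its change was -0.43 after quantile normalization and -0.24 after centring.

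Of 32 chemokine, cytokine and NF-kB target genes, 15 rose and 4 fell in all scalings (camera adjusted p = 7.04e-08, 0.000135 after quantile normalization, and adjusted p = 0.0455 with an estimated correlation). With quantile normalization and an estimated correlation the list did not pass (adjusted p = 0.11). TNFAIP3 and NFKB2, genes of NF-kB signalling, rose by 2.22 ± 0.06 and 1.82 ± 0.06, the neutrophil chemokine gene CXCL8 by 1.27 ± 0.05, and CSF1 fell by 1.33 ± 0.05, with a change of -0.78 after quantile normalization. Of 37 interferon-stimulated genes 6 rose and 5 fell in all scalings (adjusted p = 0.0253, 0.0382 after quantile normalization and 0.114 with an estimated correlation). On the deposited values 6 were called higher and 23 lower, and after quantile normalization 19 and 7. Centring left this list at adjusted p = 0.0628. OASL rose by 5.16 ± 0.10 and IFI6 by 3.35 ± 0.10, while DTX3L fell by 1.15 ± 0.07. Of 19 genes of cytosolic nucleic acid sensing, 4 rose and 7 fell, RIGI by 2.37 ± 0.09 and IRF3 by 1.30 ± 0.07 among the first and DHX58 by -1.34 ± 0.05 (-0.75 after quantile normalization) among the second, and the list did not pass (adjusted p = 0.324, and 0.986 after quantile normalization). Of 11 endogenous retroviral envelope and related genes, 3 rose and 2 fell, and that list did not pass either (adjusted p = 0.0871, and 0.331 after quantile normalization). Of 34 cancer-testis and germline genes 0 rose and 12 fell in all scalings. The median untreated level of the list, 4.65, was close to that of leukocyte markers, 4.61, so these falls lie near background and their sizes are uncertain. MAGEA4 moved from 4.92 to 3.49. The list passed on the deposited values (adjusted p = 0.00126) but not after quantile normalization (0.248), nor on the deposited values with an estimated correlation (adjusted p = 0.0502).

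The immediate-early and AP-1 list stood higher than other genes (camera adjusted p = 1.68e-07, 3.1e-05 after quantile normalization, and adjusted p = 0.08 with an estimated correlation). Of 27 members 11 rose and 0 fell, EGR1 by 3.67 ± 0.12, SPRY4 by 1.30 ± 0.08 (1.97 after quantile normalization) and DUSP6 by 1.24 ± 0.08 beside FOSB. EGR1 and SPRY4 started at 4.94 and 4.90, below the median of the untreated arrays, so their sizes too are lower bounds where those levels are background. Of 34 autophagy and lysosome genes 17 rose and 4 fell (adjusted p = 1.87e-08, 0.000924 after quantile normalization and 0.0108 with an estimated correlation). With quantile normalization and an estimated correlation this list did not pass (adjusted p = 0.11). ATG2A rose by 1.34 ± 0.05 and NBR1, an autophagy receptor gene, by 1.08 ± 0.06 (1.63 after quantile normalization), while ATG9A fell by 1.67 ± 0.07 and TFEB fell by 1.12 ± 0.05. The change of TFEB was -0.51 after quantile normalization and -0.48 after centring, and its treated level was 4.23, below the median of the treated arrays. Of 20 apoptosis genes 9 rose and 1 fell (adjusted p = 0.000176, 0.00433 and, with an estimated correlation, 0.0455). With quantile normalization and an estimated correlation it did not pass (adjusted p = 0.212). The members that rose included both BCL2L11, which promotes cell death, at 1.38 ± 0.05, and MCL1, which opposes it, at 1.15 ± 0.07. Of 22 p53 target genes 7 rose and 4 fell (adjusted p = 0.00435, 0.0093 and, with an estimated correlation, 0.159), with SESN2 at 1.73 ± 0.04 and MDM2 at 1.27 ± 0.06. Of 12 measured replication-dependent histone genes 7 rose and 2 fell (adjusted p = 1.49e-06, 0.042 and, with an estimated correlation, 0.136). H4C3 rose by 3.22 ± 0.22 and HIST1H2AH fell by 1.52 ± 0.14, with a change of -0.97 after quantile normalization. Histone genes also share sequence, and centring left this list at adjusted p = 0.058.

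Basal and squamous urothelial genes moved the other way. Of 20 measured members 14 fell and 1 rose in all scalings, with a median log2 change of -1.36 on the deposited values and -0.88 after quantile normalization. KRT5 fell by 2.35 ± 0.06 and EGFR fell by 2.78 ± 0.08, beside KRT14. The list passed after quantile normalization (camera adjusted p = 0.000453, and adjusted p = 0.11 with an estimated correlation) and not on the deposited values (0.0639). Of 24 luminal genes 6 rose and 6 fell: KRT8 by 1.68 ± 0.10 and GRHL3 by 1.40 ± 0.06 were higher, and PPARG by -1.20 ± 0.04 (-0.76 after quantile normalization) lower. Mesenchymal genes were likewise split, SPARC and SNAI1 rising by 1.96 ± 0.06 and 4.55 ± 0.24 and THBS1 changing by -1.70 ± 0.07, 2 of 23 rising and 6 falling in all scalings. On the deposited values 2 of these were called higher and 16 lower, and after quantile normalization 13 and 8. SNAI1 started at 3.92, so the size of its rise is a lower bound where that level is background. Neither the luminal nor the mesenchymal list passed (adjusted p = 0.058 and 0.671, and 0.48 and 0.279 after quantile normalization). Genes of sterol synthesis fell in part: DHCR7 fell by 1.98 ± 0.07 and MSMO1 fell by 2.63 ± 0.11, among 8 of 20 that fell, with 4 that rose (adjusted p = 0.556, and 0.576 after quantile normalization). Of 24 NRF2 target and metallothionein genes 9 fell and 5 rose (adjusted p = 0.533, and 0.279 after quantile normalization), and AKR1C1 fell by 2.30 ± 0.05 and AKR1C2 fell by 2.91 ± 0.11. Glucose use genes SLC2A1 fell by 2.15 ± 0.06 and LDHA fell by 2.11 ± 0.09, within a hypoxia and glycolysis list of 27 in which 6 rose and 7 fell (adjusted p = 0.0231, 0.279 after quantile normalization and 0.219 with an estimated correlation).

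Lists of cycling cells passed on the deposited values and not after quantile normalization, and the mitotic list passed after centring too (adjusted p = 0.00242). Of 33 mitotic genes 13 rose and 4 fell in all scalings (adjusted p = 1.87e-08, then 0.0514), with CDC25C at 1.40 ± 0.05 and CCNA2 at -1.49 ± 0.11. Of 36 replication genes 9 rose and 5 fell (0.0118, then 0.624), with CCNE2 at 1.87 ± 0.07 and POLA1 at -1.65 ± 0.09. The same held for the unfolded protein response and ATF4 list (0.0101, then 0.551), in which HERPUD1 rose by 2.06 ± 0.09 and SLC7A5 fell by 2.04 ± 0.09, for oxidative phosphorylation (0.00435, then 0.551) and for reference genes (0.0101, then 0.867), which passed after centring as well (adjusted p = 0.0483). With an estimated correlation the adjusted p of these 5 lists lay between 0.136 and 0.33. Clustered protocadherins did not pass (0.0871, then 0.0644). Markers of leukocytes and of stromal and endothelial cells, which these cultures should lack, had median control levels of 4.61 and 4.89 and did not pass (0.069 and 0.154, then 0.331 and 0.974), with 1 of 24 and 0 of 20 rising and 11 and 8 falling in all scalings. Of all 22465 genes, 6285 fell in all scalings. Such calls among genes at low levels limit what a held fall of a dim gene means. In all, 16 of 27 lists passed on the deposited values, 10 after quantile normalization and 9 in both. With an estimated correlation 3 passed on the deposited values and 0 after quantile normalization. Several lists that stood higher relative to other genes had deposited medians below 0, with -0.36 for interferon-stimulated genes, -0.20 for checkpoint and NKG2D ligands and -0.11 for p53 targets, and medians of 0.28, 0.30 and 0.37 after quantile normalization. The counts adjusted over the list alone came to 15 of 21 members for MHC class I and 27 of 32 for the chemokine list on the deposited values, in both directions together, against 15 and 27 over all genes.

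**Figure D3:**
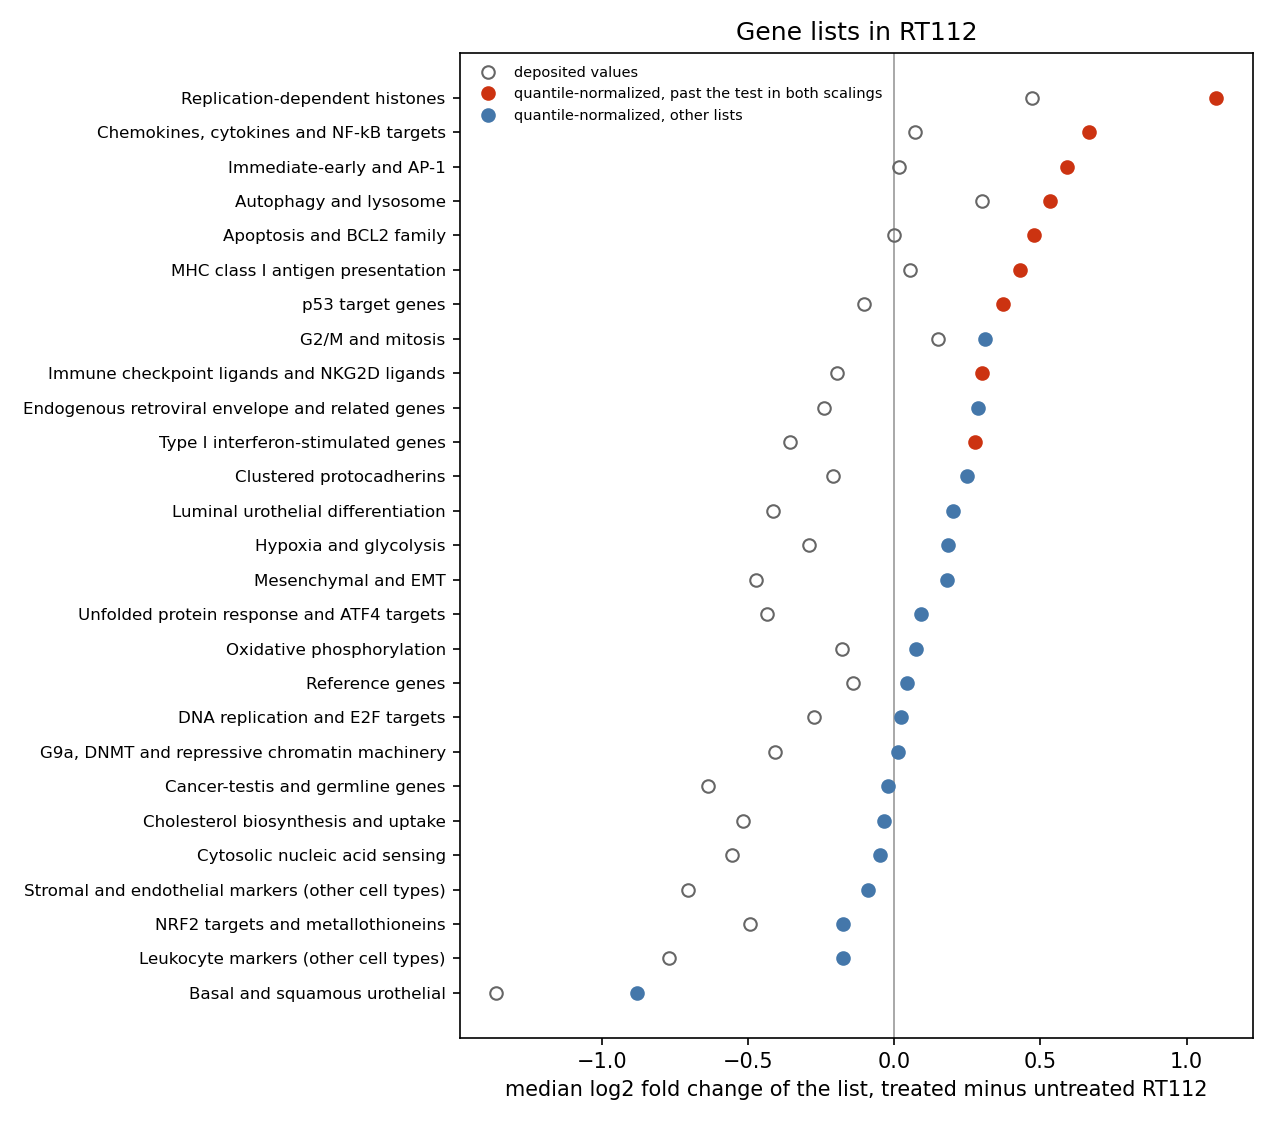
Median log2 fold change of each of the 27 gene lists in RT112, treated minus untreated, for the deposited values (open circles) and after quantile normalization (filled, red where the list passed camera in both scalings). Replication-dependent histones have the highest median after quantile normalization, 1.10, and basal and squamous genes the lowest, -0.88, and every deposited median lies lower than the quantile-normalized one.

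The treated arrays of both lines, which shared many exactly tied values, were compared with each other. In treated 5637 the interstitial collagenase gene MMP1 stood at 17.85 ± 0.08 (SD, n = 3). In treated RT112 it stood at 5.91 in all 3 arrays, with an SD of 0. The log2 difference was 11.94 ± 0.10 (SE, adjusted p = 1.31e-10, limma), and this SE rests in part on that SD. TNFRSF10D, a decoy receptor gene for TRAIL, was higher by 6.97 ± 0.12, the N-cadherin gene CDH2 by 6.88 ± 0.08, CDKAL1 by 6.57 ± 0.18 and the matrix gene TNC by 6.33 ± 0.06. The carboxylesterase gene CES1 was lower in 5637 by a log2 difference of -10.57 ± 0.11, TCN1 by -8.74 ± 0.16, the keratin gene KRT13 by -8.24 ± 0.07, S100P by -7.68 ± 0.12 and AKR1B10 by -7.57 ± 0.18. In treated 5637 CES1, KRT13, S100P and AKR1B10 stood at 4.38, 4.50, 4.44 and 4.29, about the array median, and in treated RT112 TNFRSF10D stood at 4.57, so these sizes are lower bounds where such levels are background. In all, 3845 genes were higher and 3547 lower in treated 5637, and 3678 and 3032 were called in the same direction in all 3 scalings. These differences hold the difference between the lines and any difference of their responses together. Of 318 transcript clusters more than 8-fold apart between the treated lines, untreated RT112 lay nearer to treated RT112 in 279 (87.7%), in 94.9% of the 196 that were higher in 5637 and in 76.2% of the 122 that were higher in RT112.

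The comparison of treated with untreated 5637 could not be made gene by gene, because beyond the first rows the transcript-cluster values of the untreated 5637 arrays did not match those of the other arrays in the same rows. Read row by row as deposited, 4000 genes would differ by at least 16-fold between treated and untreated 5637, against 46 in RT112. The windows of 60 rows correlated with treated 5637 at a median r of -0.0143 in the same rows and 0.878 at the best offset. No value of a gene in untreated 5637 is given.

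**Figure D4:**
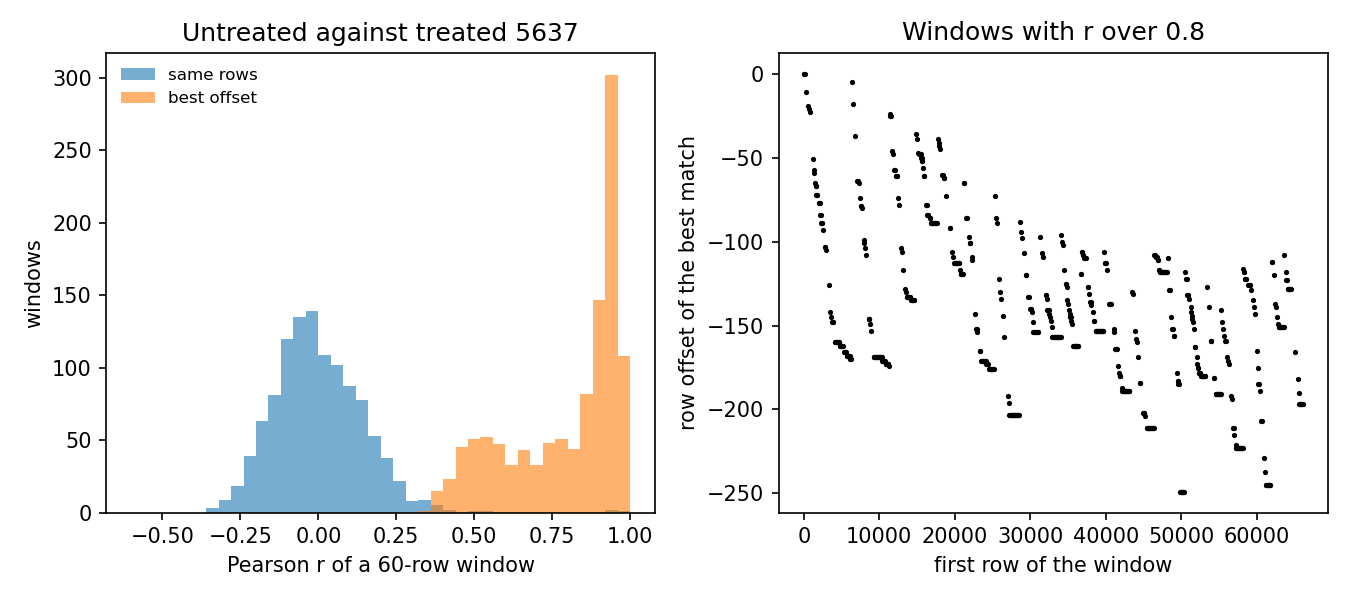
Left, Pearson's r of untreated against treated 5637 in 1125 windows of 60 transcript-cluster rows, in the same rows and at the best offset up to 300 rows. Right, the offset of the 683 windows with r over 0.8 against their first row; the offsets lie between -249 and 0 rows, with 3 windows at 0.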

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

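Of the tests in this part, the splits of the samples were planned before their results were seen, and the others were chosen, or in the case of the other multi-copy families redefined, after the result was seen.

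Among 42204 transcript clusters without a gene in the annotation, which entered no comparison of genes, 333 were at least 4-fold higher in treated RT112 in all 3 scalings and 140 at least 4-fold lower. The untreated 5637 arrays, which entered no comparison either, matched the treated 5637 arrays at another row offset in 60.4% of windows of 60 rows.

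Most genes called in RT112 were lower on the deposited values. Separate scaling of treated and untreated arrays is a candidate explanation that the ties do not decide. A median pair of treated arrays of different lines shared 7330 exactly tied rows, and a median pair of treated and untreated RT112 arrays shared 0. Untreated arrays hardly tied with each other, with a median of 12 rows in RT112 and 5 in 5637. Few ties with treated arrays are therefore no sign of separate scaling by themselves. The many ties among treated arrays, also of different lines, and the array medians set treated arrays apart from untreated ones. These medians averaged 4.43 in treated RT112 and 4.38 in treated 5637, against 5.07 and 5.38 untreated. This pattern goes with separate processing without showing it, and the untreated lines differed in median too. A real fall of most transcripts stays open, since quantile normalization, after which 52.1% of calls were lower, evens out totals by construction. Different hybridization batches stay open too, as no label gives a batch: all 23 background probe sets were lower in treated RT112, with a median log2 change of -0.24 and a range of -0.95 to -0.04, and 76 of 92 ERCC probe sets were lower, with a median of -0.37. The background changes differed with the number of GC bases, at -0.13 for 12, -0.38 for 20 and -0.95 for 24. At the low end they followed no steady order, at -0.35 for 3, -0.77 for 4, -0.14 for 5 and -0.04 for 7. Held genes are not protected from a shift of that kind. The 10 splits of the 6 RT112 arrays are too few for a share under 0.05, with 19093 genes called in the real split, 1 of 10, and at most 0 in another.

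Over nearly all of the table, the untreated 5637 values matched no other array row by row. Failed arrays are argued against by the lowest r between the 3 arrays, 0.983, and a response of nearly all genes by r = 0.0296 with untreated RT112. Values standing in the rows of other probe sets are a candidate explanation, with 680 of 1125 windows (60.4%) over r = 0.8 at another offset, 3 in the same rows and 0 in reversed order. How the rows came to differ was not tested.

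All 8 measured USP17-like genes were higher in treated RT112. Separate scaling is argued against by the smallest rise in any scaling, 6.96 on the log2 scale. A rise of all multi-copy families listed was not seen: of 214 members of 18 other families, 17 (7.94%, exact 95% interval 4.70% to 12.4% with members taken as independent) were higher in all 3 scalings, and of all genes 10.8%. The 18 families include REXO1L and FRG2, 2 families seen to rise beforehand, and 13 of the 209 members of the others were higher. KRTAP gave 87 of the members, 3 of them higher, and DEFB 30, with 0 higher, so these dominate the pooled share. By family, 2 of 2 REXO1L, 2 of 3 FRG2 and 3 of 10 POTE genes were higher, against 0 of 15 FAM90A, 0 of 9 PRAMEF and 0 of 6 NPIP genes. Such calls require a rise on the deposited values, where the median change of all genes was -0.57. After quantile normalization the median change was 0.59 for ZNF705, 0.49 for GOLGA8 and 0.42 for GOLGA6 genes. It was -0.10 for DEFB, -0.19 for PRAMEF and -0.20 for KRTAP genes. How alike the copies of a family are was not measured, so a rise confined to near-identical copies stays open. Shared probes between the 8 copies stay open because no probe sequences were used here, and a response of these genes to CM272 stays open too.

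Between treated 5637 and treated RT112 the real split called 7392 genes and the highest other split 0, and the 10 splits are too few for a share under 0.05, with 1 of 10 as large.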

How the results depend on the processing

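The comparison of the treated lines, the fit of 12 arrays, the omission of genes with equal replicates and quantile normalization with an estimated correlation were chosen after seeing the data. In RT112, 2433 genes were higher and 16660 lower, with 16 lists past the threshold. Quantile normalization gave 7336, 7984 and 10 lists, and centring on medians 8937, 6285 and 9. All probe sets tested singly gave 5754 higher and 49377 lower, and 6276 and 6547 between the treated lines, from more features. A 2-fold minimum gave 642 and 3986, and 925 and 637 between the lines. Lists past the threshold numbered 3 with an estimated correlation, 26 with fry, 0 with quantile normalization and an estimated correlation, and 10 without genes that had equal replicates, where 2078 genes were higher and 11998 lower of fewer tested. The cause was not tested. Fry asks whether a list changed at all, and camera whether it changed relative to other genes, so their counts are not alike. On the deposited values fry gave interferon-stimulated genes as lower (adjusted p = 0.000288), where camera gave them as higher.

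Without each array of the fit in turn, 2296 to 2432 genes were higher, 16243 to 16607 lower and 16 to 17 lists passed. The fit of 12 arrays gave 2166, 15733 and 18. Whether the replicate numbers pair the samples is not known. The deviations of arrays with the same number correlated at -0.09, -0.07 and -0.06 in RT112, which shows no sign of pairing. Arrays with different numbers were not compared, so pairing is not excluded. The replicate block gave 2289, 16206 and 17 lists.

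Of 3218 values of named genes in RT112 under the alternatives, 3165 kept direction and side of the threshold, 40 lost and 2 gained the threshold, and 11 reversed in 6 genes. Between the lines all 219 kept both. MMP1, with equal values in treated RT112, was not tested where genes with equal replicates were left out. After quantile normalization EHMT1 changed by 0.059, DNMT3B by 0.59 and PCDHB6 by 0.25. After centring EHMT1 changed by 0.19, DNMT3B by 0.62, PCDHB6 by 0.28, HHLA2 by 0.054, PCDHB3 by 0.084 and RPS18 by 0.041. Without single arrays DNMT3B lay between -0.11 and 0.069, and at 0.0077 without the second untreated array. Other settings of the comparisons with untreated 5637 were not run, as those comparisons were not made. Genes near background limit what these arrays resolve.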

Other observations

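The genes of this part were chosen after their values were seen. In the RefSeq order of assembly GRCh38.p14, the 5 nearest protein-coding genes on the preceding side of TEX14 also rose in all 3 scalings. On the deposited values SEPTIN4 rose by a log2 change of 3.71, HSF5 by 2.34, RNF43 by 2.07, MTMR4 by 1.85 and SUPT4H1 by 1.56. Genes of other types were left out of this order. The next on that side, TSPOAP1, changed by -0.67 on the deposited values and by -0.02 after quantile normalization. The levels of SEPTIN4 and HSF5 in untreated RT112, 4.73 and 3.93, lay below the array median, so their sizes are lower bounds where those levels are background. On the other side the nearest protein-coding gene, IGBP1C, was not analysed here. PPM1E and SKA2 rose in all 3 scalings, by 0.55 and 1.82 on the deposited values and by 1.23 and 2.00 after quantile normalization, while RAD51C, TRIM37 and PRR11 were not called alike, with -0.20, -0.22 and -0.03 on the deposited values and 0.15, 0.23 and 0.12 after quantile normalization.

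Among single genes in RT112, POLR2A, which encodes the largest subunit of RNA polymerase II, rose by 4.51 ± 0.06 (SE, n = 3), HEXIM1, an inhibitor of the elongation factor P-TEFb, by 4.10 ± 0.06 and the general factor gene GTF2B by 4.05 ± 0.10. TXNIP rose by 4.52 ± 0.11, SLIT2 by 5.85 ± 0.13 from 4.74, also below that median, the chemokine receptor gene CXCR4 by 4.83 ± 0.13 and EPHA4 by 4.75 ± 0.16. HIF1A, the hypoxia-inducible factor gene, fell by 2.77 ± 0.05 and ACACA, an enzyme gene of fatty acid synthesis, fell by 2.56 ± 0.09. LRP8 fell by 2.88 ± 0.09.

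Of the multi-copy families, 6 of 6 measured NPIP genes were lower in all 3 scalings, with a median log2 change of -1.34 after quantile normalization, and 2 of 2 measured REXO1L genes were higher, with a median of 8.35. Copies of these families resemble each other, so the values of single copies are uncertain.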
